A study of Homo sapiens with 8 samples.

How the data were processed

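The data are the deposited table of 8 Affymetrix arrays of A549 cells in 4 groups of 2: control siRNA without glucose, control siRNA with glucose, SRC-1 siRNA without glucose and SRC-1 siRNA with glucose. Groups and replicate numbers were taken from the sample labels, which call the 2 arrays of a group biological replicates. Nothing else is said of how the cultures were kept apart, so the p-values measure the spread between these arrays. Per the labels' protocols, transfection used DharmaFECT 1, RNA was isolated with RNeasy columns, and biotinylated cRNA was made and hybridized by the standard Affymetrix procedure.

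The values in the deposited table lie between 1.98 and 14.7 with no missing value and were used as log2 signal per probe set. The log base was inferred from the values. Neighbouring hybridization spikes, added at known dilutions, stood 1.91, 1.92 and 2.14 units apart, which fits a base of 2 and not of 10. The array medians over all probe sets lay between 4.97 and 5.01, so the arrays were on a common scale as deposited. How the authors corrected the background, summarized probes and normalized the arrays is not given in the sources used here. Detection calls and scanner files were not used here, so no signal could be set against its background, and a fold that starts or ends at a low signal may be compressed.

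Probe sets were named through the platform annotation supplied with the table, and gene names were compared with the RefSeq gene table of assembly GRCh38.p14 through the Entrez identifiers. Of 54675 probe sets, 62 were controls, 41091 had 1 gene, 1801 had several genes and were named by none, and 11721 were not listed and stayed unnamed. Of those with 1 gene, 41037 matched by identifier and 54 kept the name in the annotation, and 0 symbols had to be changed. No coordinates are given, since no genome build is named for the table. Probe sets whose mean over the 8 arrays was below the 40th percentile of the probe sets with 1 gene (log2 4.80) were left out. For each gene the probe set with the highest mean was kept, which left 13584 genes. Genes of which this annotation names no probe set were not analysed here.

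All 8 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3) with a mean for each group, so that the groups share an estimate of the spread with 4 residual degrees of freedom and 4.35 prior degrees of freedom. Contrasts gave the effect of glucose with each siRNA, the effect of SRC-1 siRNA in each medium and averaged over both, and their interaction. Tests were two-sided and moderated (eBayes), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are differences of group means on the deposited log2 scale, given with their SE, and intervals are 95% intervals. A permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so calls of single genes rest on the model's shared spread. Gene lists were tested with camera at a preset correlation between genes of 0.01, with an estimated correlation and with fry as alternatives, and Benjamini-Hochberg adjustment over the 36 lists of a comparison. The lists, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined. Each list is textbook membership and was not chosen on these arrays.

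For each comparison the text draws on NCOA1 and a fixed set of genes of its family, of glucose sensing, stress and energy metabolism. Not every gene of this set is given for every comparison, and its family member NCOA3 is not reported. The text also names the 10 largest rises and the 10 largest falls among called genes whose 2 groups do not overlap, or 5 each for the average and the interaction. Up to 4 members of a list with the smallest p are named as well. Where no gene passed, the 5 smallest p in each direction are named. The further probe sets of SS18, GPR180 and KLHL5 were chosen for a closer look after the results were seen.

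The alternatives were quantile normalization, centring on array medians, no filter, a filter at the 60th percentile and the mean of a gene's probe sets. Another left out probe sets whose names end in _s_at or _x_at, called cross-hybridizing here. The name alone does not show that such a probe set binds another gene. Further alternatives were a prior that follows mean expression, array weights, a fit of only the groups compared and a replicate block. Each array was also left out in turn, and a threshold of 1.5-fold was applied. RNA quality was read from the 3' and 5' control probe sets of GAPDH and beta-actin with exact permutation tests. The fit was tested on simulated arrays with the mean and spread of each of 13584 genes, in 20 simulations per comparison with 200 changed genes each. For the averaged knockdown effect it recovered 55.2% of 1.2-fold, 99.5% of 1.5-fold and 99.9% of 2-fold changes, with 11.2 false calls on average. For the glucose effect with control siRNA it recovered 93.4% of 1.5-fold changes. With fewer changed genes the adjusted threshold is stricter, so these shares are upper values for a comparison in which few genes change. Camera called 20 of 20 simulated lists of 30 genes shifted by 0.3 and 0 of 20 unshifted lists in each comparison. The simulated genes varied independently of each other, so this does not show how camera behaves where the members of a list are correlated.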

Results

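A549 cells, an established line of human lung adenocarcinoma, were transfected with a control small interfering RNA (siRNA) or with one that targets steroid receptor coactivator 1 (SRC-1), the nuclear receptor coactivator encoded by NCOA1. After 36 h in medium with 10% dialyzed serum, from which small molecules have been removed, the cells were given medium with or without glucose. The length of this last step is not given in the sources used here. RNA from 4 groups was hybridized to 8 genome-wide Affymetrix 3' expression arrays, 2 arrays per group, which the labels call biological replicates. The series asks how loss of SRC-1 changes gene expression in each medium, and its title names the balance of glucose and of NAD(+) and NADH. Of the 54675 probe sets in the deposited table, 41091 were tied to a single gene, and after a filter on dim probe sets 13584 genes were tested. The correlation of log2 signals between the 2 arrays of a group lay between 0.997 and 0.998. The number of arrays limits the precision, and the median standard error (SE) of a log2 difference between 2 groups was 0.0834. The first principal component held 86.1% of the variance and parted the 4 arrays with glucose from the 4 without.

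The targeted mRNA was examined first. With glucose, the NCOA1 signal fell from 8.51 ± 0.12 (SD, n = 2) with control siRNA to 5.32 ± 0.20 with SRC-1 siRNA on the log2 scale, a 9.10-fold loss (adjusted p = 1.44e-05, limma). Without glucose it fell from 8.29 ± 0.073 to 5.15 ± 0.094, an 8.78-fold loss (adjusted p = 1.65e-05). All 4 NCOA1 probe sets fell in both media, and the other 3 fell between 4.02-fold and 6.21-fold. All 4 knockdown arrays lay below all 4 control arrays, so the labels and the measured target go the same way. After knockdown the signal of the main probe set stood at the 46.9th percentile of probe sets, near the dim range, so the fold may be compressed. NCOA2, which encodes a close relative of SRC-1, differed by 0.022 on the log2 scale over both media (95% interval -0.14 to 0.18) and was not called. SRC-1 protein was not analysed here.

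**Figure D1:**
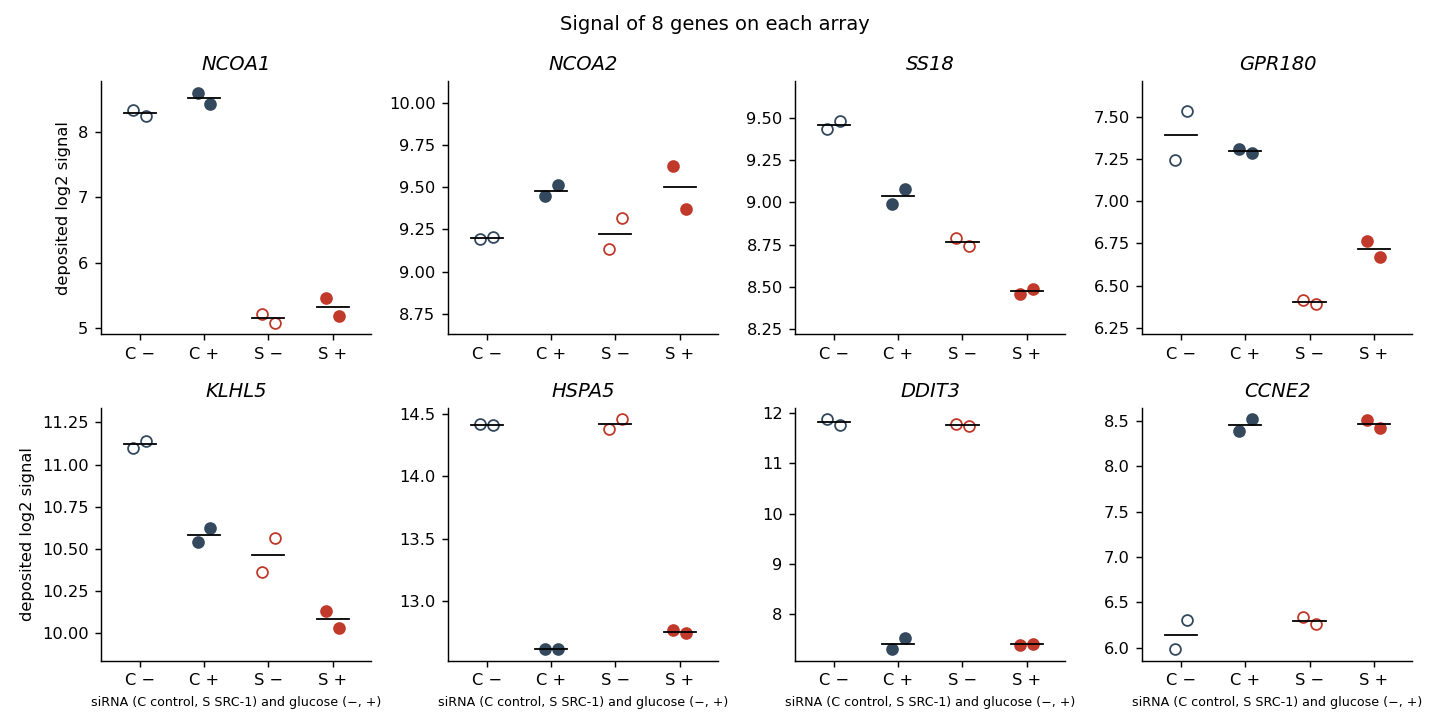
Deposited log2 signal (vertical axis) of 8 genes on each of the 8 arrays, by siRNA (C control, dark; S SRC-1, red) and glucose (open points without, filled points with); each point is 1 array and each bar the mean of 2 arrays, with a vertical range of its own in each panel. NCOA1 fell with SRC-1 siRNA from 8.51 to 5.32 with glucose, while HSPA5, DDIT3 and CCNE2 were parted by glucose.

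The effect of glucose with control siRNA addresses the response of transfected cells in which SRC-1 was not targeted. No untransfected cells are among the groups. Genes of the stress response in the endoplasmic reticulum (ER) were lower with glucose than without, and genes of DNA replication and cell division were higher. HSPA5, the main ER chaperone, was 3.48-fold lower with glucose (-1.80 ± 0.063 on the log2 scale, SE, n = 2 per group). Its signal on the control siRNA arrays without glucose (14.42 and 14.41) lay near the highest signal of those arrays (14.64 and 14.69). The folds of HSPA5 may therefore be compressed. DDIT3, the stress-induced transcription factor CHOP, was 21.2-fold lower (-4.40 ± 0.086). CCNE2, a cyclin of the entry into S phase, was 4.98-fold higher (2.31 ± 0.11), and the replication factor MCM10 was 3.89-fold higher (1.96 ± 0.073). In all, 6142 of 13584 genes passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), 3211 higher and 2931 lower, and of these 292 rose and 293 fell by at least 2-fold.

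The list of ER chaperones and ER-associated degradation moved almost as a whole. Of its 33 tested members, 32 were lower with glucose and 0 higher, both over all genes and adjusted over the list alone, with a median of -1.23 on the log2 scale. CRELD2 (-2.98 ± 0.072), the chaperone HYOU1 (-2.72 ± 0.063), HERPUD1 (-2.52 ± 0.065), which takes part in degradation, and the disulfide isomerase PDIA4 (-2.04 ± 0.066) had the smallest p. In the ATF4 and CHOP branch of the integrated stress response, 29 of 32 members were lower and 1 higher (median -0.99), with the same counts adjusted over the list alone. Beside DDIT3 these held ATF3 (-3.67 ± 0.11), STC2 (-2.77 ± 0.079) and NUPR1 (-2.09 ± 0.063), all stress-induced. ASNS, which makes asparagine, fell by 4.94-fold (-2.30 ± 0.073), and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, by 4.82-fold (-2.27 ± 0.064). Of 17 cytosolic tRNA synthetases, 12 were lower and 2 higher, among them WARS1 (-2.04 ± 0.062) and SARS1 (-1.48 ± 0.081). By camera, the set test of limma, the adjusted p of these 3 lists was 1.19e-19, 7.67e-17 and 2.37e-05. With an estimated correlation between genes the first and the second kept their calls (adjusted p = 0.0366 for both), and the tRNA synthetases did not (adjusted p = 0.0938).

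Cell cycle genes moved the other way. Of 31 G1/S and DNA replication genes, 29 were higher with glucose and 0 lower, or 30 higher adjusted over the list alone, with a median of 1.10. MCM6 (1.84 ± 0.076) and MCM7 (1.47 ± 0.066), both subunits of the replicative helicase, were among them. GINS2 (1.42 ± 0.064) was called higher on its brightest probe set but not on the one left when cross-hybridizing probe sets were set aside (-0.00046). Of 30 G2/M and mitosis genes, 26 were higher and 0 lower, and adjusted over the list alone 27 were higher and 1 lower. The mitotic motor KIF11 (1.23 ± 0.085) and the kinase AURKA (0.93 ± 0.062) had the smallest p, followed by KIF20A (0.86 ± 0.065) and BUB1B (0.78 ± 0.074). The camera adjusted p was 4.21e-17 for G1/S and 7.73e-09 for G2/M, and with an estimated correlation neither list passed (adjusted p = 0.153 and 0.0938).

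Lipid synthesis genes were higher with glucose. Of 19 cholesterol synthesis and uptake genes, 15 were higher and 1 lower, and 17 were higher adjusted over the list alone. INSIG1, a sterol sensor of the ER, differed by 1.60 ± 0.15 and lanosterol synthase LSS by 1.22 ± 0.10. Of 13 fatty acid synthesis genes, 10 were higher and 0 lower, by either adjustment, including the fatty acid synthase FASN (0.76 ± 0.065) and the desaturase SCD (0.85 ± 0.073). Of 22 glycolysis genes, 13 were higher and 2 lower, by either adjustment. The glucose transporter SLC2A3 differed by 0.67 ± 0.095, the regulatory enzyme PFKFB3 by 0.79 ± 0.086 and LDHA, lactate dehydrogenase, by 0.29 ± 0.060. HK2, a hexokinase that takes the first step of glycolysis, went against its list and was 4.33-fold lower with glucose (-2.12 ± 0.11). The camera adjusted p of these 3 lists was 7.41e-06, 5.52e-04 and 0.0169, and with an estimated correlation none passed (adjusted p = 0.313, 0.270 and 0.271).

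Signalling and degradation lists were lower with glucose. Of 18 immediate early genes, 16 were lower and 0 higher, and adjusted over the list alone 1 was higher. Among the members that fell were the phosphatases DUSP5 (-1.69 ± 0.068) and DUSP6 (-1.34 ± 0.091). Of 21 NF-kappaB targets and cytokines, 13 were lower and 3 higher, and the chemokines CXCL2 (-2.21 ± 0.077) and CXCL8 (-2.07 ± 0.091) had the smallest p. Of 27 lysosome and autophagy genes, 16 were lower and 3 higher, or 17 and 4 adjusted over the list alone. The autophagy genes WIPI1 (-2.28 ± 0.097) and MAP1LC3B (-1.40 ± 0.066) fell, and GLA, a lysosomal galactosidase, rose (0.79 ± 0.069). Of 19 hexosamine and nucleotide sugar genes, 10 were lower and 4 higher, or 13 and 4 adjusted over the list alone. GFPT1, the entry enzyme of the hexosamine pathway, differed by -1.62 ± 0.079, and OGA, which removes the sugar GlcNAc from proteins, by 1.45 ± 0.084. Of 21 TGF-beta and YAP targets and matrix genes, 10 were lower and 2 higher, or 13 and 3 adjusted over the list alone, among them CCN2 (-1.13 ± 0.083). Cytosolic ribosomal protein genes shifted little, with 5 of 51 lower, 0 higher, a median of -0.072 and 2 lower adjusted over the list alone. Camera called all 6 lists lower with the preset correlation, the ribosomal list at an adjusted p of 0.0362, which quantile normalization moved to 0.118. None passed with an estimated correlation (adjusted p = 0.313 for immediate early genes, 0.612 for NF-kappaB targets, 0.153 for lysosome and autophagy, 0.313 for hexosamine genes, 0.654 for TGF-beta and YAP targets and 0.654 for ribosomal proteins).

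Camera called none of the lists of mitochondrial energy metabolism with glucose. Fry, the other set test of limma, asks whether members changed at all, not whether they changed more than other genes. Of all tested genes 45.2% were called, and fry in a single direction called 25 of 36 lists. It called NAD metabolism (adjusted p = 0.00202) and gluconeogenesis (5.58e-04) lower. The pentose phosphate pathway (0.00998), the TCA cycle (0.0367) and fatty acid oxidation (0.0489) were called higher. In gluconeogenesis PCK2 stood at -2.27 and the other members between -0.28 and 0.25. Mixed fry, which counts changes in either direction, called 33 of 36 lists, complex I among them (9.28e-06). A smaller share of complex I genes was called than of all genes. Of 46 genes of respiratory complex I, the NADH dehydrogenase, 8 were higher and 10 lower, and adjusted over the list alone 8 were higher and 9 lower (median -0.021, camera adjusted p = 0.689). NDUFV1, a catalytic subunit, differed by -0.34 ± 0.083 and the assembly factor NDUFAF3 by -0.64 ± 0.070, while NDUFS1 (-0.16 ± 0.074) and NDUFA9 (-0.023 ± 0.070) were not called. NDUFV3 was called lower (-0.71 ± 0.060), but its other probe set gave 0.15. Of 30 genes of NAD synthesis and use, 4 were higher and 13 lower, with the same counts adjusted over the list alone (median -0.25, camera adjusted p = 0.131). NADK, which turns NAD into NADP, was lower (-0.65 ± 0.062), as was the nicotinamide riboside kinase NMRK1 (-0.71 ± 0.064), and TDO2, which breaks down tryptophan, was higher (1.25 ± 0.10). NAMPT, the main enzyme of NAD salvage, was called lower (-0.34 ± 0.10). The brightest of its probe sets with names not ending in _s_at or _x_at gave 0.040. Which of them reads NAMPT better was not tested. The remaining energy lists also held members on either side. Complexes II to V had 6 higher and 4 lower of 36, the mitochondrial ribosome 18 and 13 of 67, and the TCA cycle 9 and 4 of 28. In the TCA cycle list PDK4, a kinase that shuts off pyruvate dehydrogenase, rose 3.74-fold (1.90 ± 0.098) and the opposing phosphatase PDP1 fell (-1.16 ± 0.074). The NADH shuttles had 5 higher and 3 lower of 11, with the aminotransferase GOT1 at -1.45 ± 0.065 and the aspartate-glutamate carrier SLC25A12 at 1.26 ± 0.079. Fatty acid oxidation had 5 and 4 of 24, the pentose phosphate pathway 4 and 2 of 9, gluconeogenesis 1 and 2 of 5, and regulators of mitochondrial biogenesis 5 and 3 of 16.

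Genes driven by the sugar-sensing factors MondoA and ChREBP went both ways, with 2 higher and 4 lower of 10 (camera adjusted p = 0.355, fry 0.0367). TXNIP, the best known of them, had a signal of 6.28 without and 6.05 with glucose and was not called (-0.22 ± 0.11), and neither was ARRDC4 (0.26 ± 0.14) or the glucose transporter SLC2A1 (-0.15 ± 0.082). ARRDC3 rose (0.62 ± 0.10) and the clock gene BMAL1 fell (-0.70 ± 0.064). Of 18 nuclear receptor coregulators, 6 were higher and 1 lower, with NCOA5 at 0.66 ± 0.089 and NCOA2 at 0.28 ± 0.099. NCOA1 itself differed by 0.22 ± 0.11 on its brightest probe set and was not called, but another of its 4 probe sets was called higher with glucose (0.36 ± 0.087, adjusted p = 0.0160).

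By size alone, the largest fall with glucose was that of HSPA6, an inducible heat shock protein, at 54.1-fold (-5.76 ± 0.29), although its 2 arrays without glucose lay apart (SD 0.77). NIBAN1 (-4.13), RAB39B (-4.06), BEX4 (-3.56), BEX2 (-3.31), EML2-AS1 (-2.94) and ALDH1L2 (-2.92), a mitochondrial folate enzyme, completed the 10 largest falls with DDIT3, ATF3 and CRELD2. The 10 largest rises were those of ID4 (2.36 ± 0.097), CCNE2, the E2F family members E2F8 (2.28 ± 0.090) and E2F2 (2.04 ± 0.16), the chromatin remodeller HELLS (2.27 ± 0.13), the ubiquitin ligase RNF43 (2.07 ± 0.098), HSPA2 (2.06 ± 0.075), NOVA1 (2.05 ± 0.11), PCGF3 (2.15 ± 0.085) and a probe set assigned to MIR3682 (2.21 ± 0.14). PCGF3 is uncertain, since 1 of its 3 probe sets was called the other way, and an array of this kind does not measure a mature microRNA. Where a signal ends near the dim range, as for BEX4 with glucose, the fold is likewise uncertain.

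**Figure D2:**
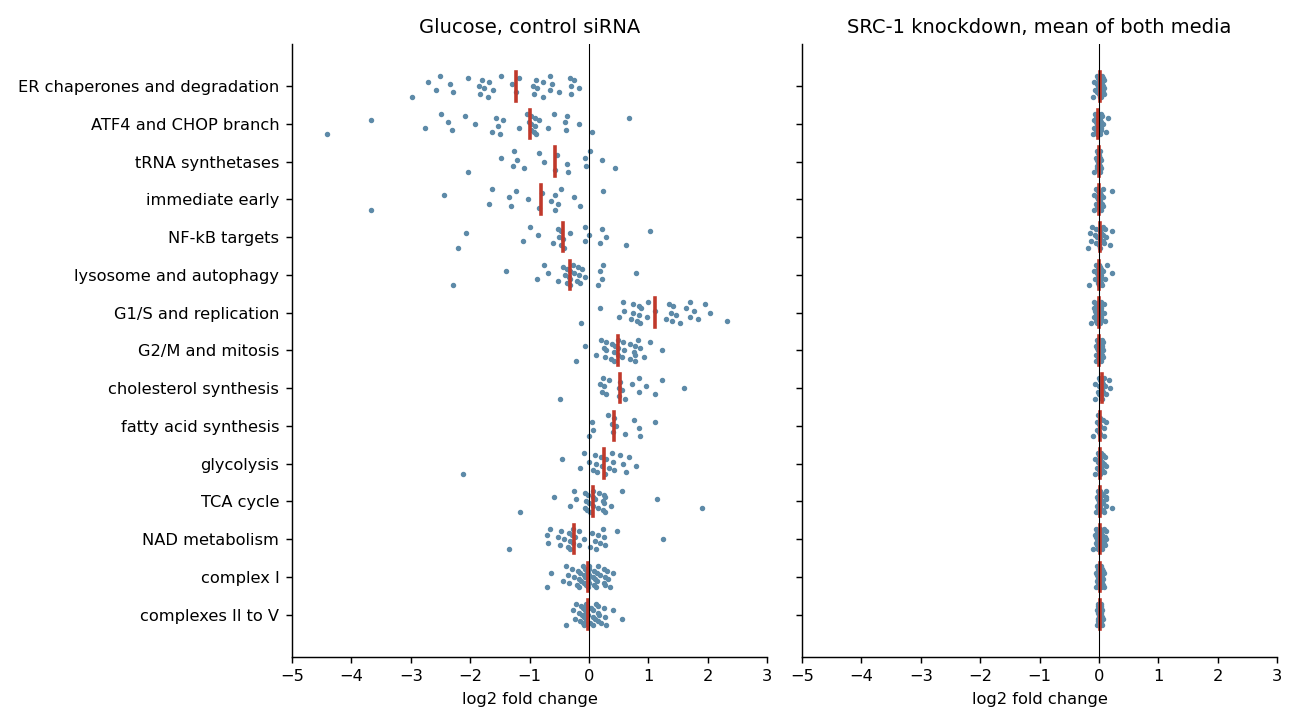
Log2 fold change (horizontal axis) of the tested members of 15 gene lists; each point is 1 gene and each red bar the median of its list. With glucose (left, control siRNA) the ER list has a median of -1.23 and the G1/S list of 1.10; with SRC-1 knockdown averaged over both media (right) the complex I list has a median of 0.0088.

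The same question in cells with SRC-1 siRNA gave a like picture. ER chaperones and ATF4 targets were lower with glucose, and cell cycle genes higher. HSPA5 was 3.17-fold lower (-1.67 ± 0.063), DDIT3 20.5-fold lower (-4.36 ± 0.086), and CCNE2 4.50-fold higher (2.17 ± 0.11). In all, 6070 genes passed, 3348 higher and 2722 lower, and of these 320 rose and 276 fell by at least 2-fold. Of the ER list 31 of 33 members were lower (median -1.18), of the ATF4 list 30 of 32 (median -0.95), and of the G1/S list 29 of 31 were higher (median 1.21). Of the G2/M list 25 of 30 were higher, and of the cholesterol list 16 of 19. Camera called 14 of 36 lists, and with an estimated correlation only the ER and ATF4 lists passed (adjusted p = 0.0353 for both), while G1/S (0.179), G2/M (0.102) and cholesterol synthesis (0.324) had the larger adjusted p values in brackets. Complex I had 8 members higher and 9 lower of 46, and NAD metabolism 3 and 10 of 30. Camera called neither list, and fry called NAD metabolism lower (adjusted p = 0.00328) and complex I only in its mixed form (1.11e-05, against 0.143 in a single direction). The 10 largest falls were those of HSPA6 (-5.60), DDIT3, NIBAN1 (-4.20), RAB39B (-4.01), ATF3 (-3.54), BEX4 (-3.33), BEX2 (-3.26), EML2-AS1 (-3.17), CRELD2 (-3.05) and ALDH1L2 (-2.80). Among the 10 largest rises, ZNF367 (2.28 ± 0.13) and the Wnt target AXIN2 (2.10 ± 0.16) joined ID4, HSPA2, HELLS, E2F8, CCNE2, RNF43, PCGF3 and MIR3682. ARRDC4 was called higher here (0.59 ± 0.14), but the difference between the arms was not (interaction 0.33 ± 0.20, adjusted p = 0.999). TXNIP (0.013 ± 0.11) was not called.

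The 2 glucose effects shared no array. Across genes, which are not independent replicates, their log2 changes had a Pearson correlation of 0.956 and a Spearman correlation of 0.901. A total of 2802 genes were called higher in both arms, 2361 lower in both and 4 in opposite directions, where independent lists of these sizes would share 791 and 587.

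**Figure D3:**
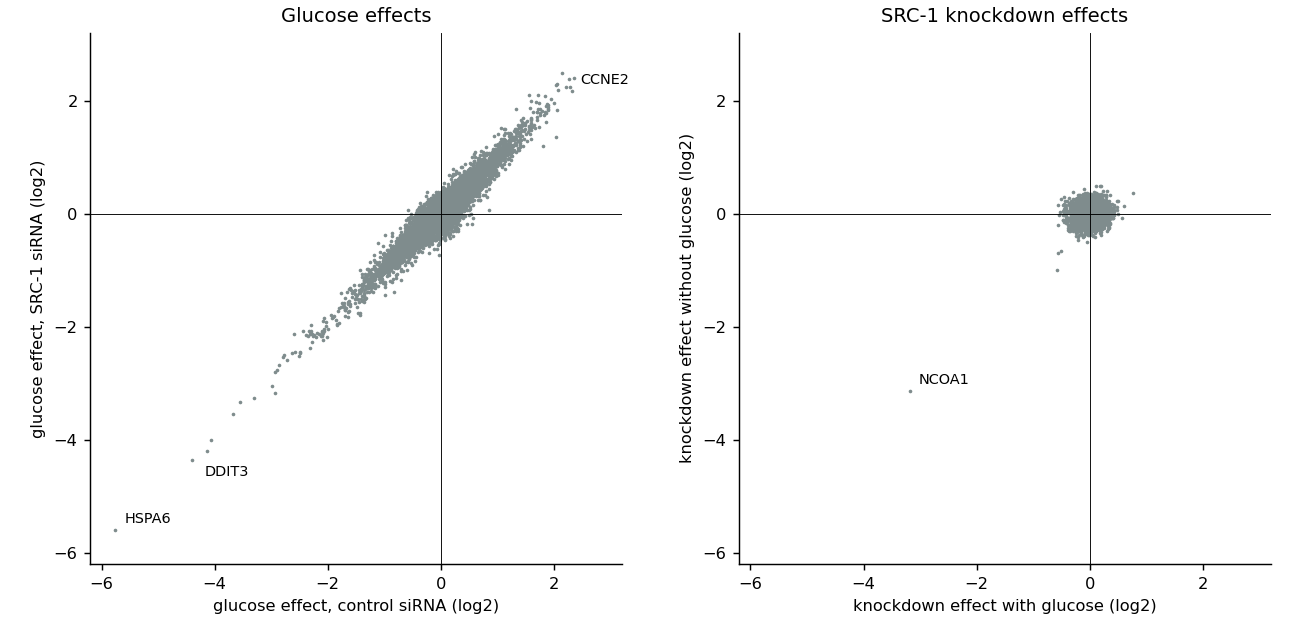
Log2 effect of glucose with SRC-1 siRNA (vertical) against that with control siRNA (horizontal) on the left, and of SRC-1 knockdown without glucose (vertical) against that with glucose (horizontal) on the right; each point is 1 of 13584 genes and both panels have the same axes. The glucose effects lie along a diagonal (r = 0.956), and in the right panel NCOA1, at -3.19 and -3.13, stands apart from the other genes.

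SRC-1 knockdown with glucose asks what the coactivator contributes in fed cells. NCOA1 was the only gene of 13584 to pass in limma, and 781 genes had an unadjusted p below 0.05, where 679 are expected by chance. That number depended on the processing, with 645 under array weights and 808 with a replicate block. Complex I had a median change of 0.017 and none of its 46 members was called, with NDUFS1 at -0.023 ± 0.074, NDUFV1 at 0.11 ± 0.083 and NDUFA9 at 0.055 ± 0.070. None of the 30 NAD metabolism genes was called either (median 0.023), and NAMPT differed by 0.028 ± 0.10. HSPA5 (0.14 ± 0.063), ASNS (0.072 ± 0.073), HK2 (0.054 ± 0.11) and TXNIP (0.061 ± 0.11) were not called. Neither camera nor fry in a single direction called any of the 36 lists. Mixed fry called 3, coregulators (adjusted p = 2.28e-04), which hold NCOA1, sugar-responsive genes (0.00659) and NADH shuttles (0.0460). The only members of any list to pass when adjusted over the list alone, other than NCOA1, were 1 sugar-responsive gene, MLXIPL, which encodes ChREBP (-0.47 ± 0.076, adjusted p = 0.316 over all genes), and 1 gene of ribosome biogenesis. MLXIPL passed in the same way for the averaged effect (-0.25 ± 0.054) and the interaction (-0.44 ± 0.11). Both contain the difference with glucose, so they are not separate evidence. Adjustment over a list alone also does not allow for the number of lists, so chance is not excluded. For 98.1% of genes the 95% interval lay within a 1.5-fold change in either direction. In simulated arrays with 200 changed genes, this comparison recovered 95.7% of 1.5-fold and 14% of 1.2-fold changes.

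Without glucose, SRC-1 knockdown lowered NCOA1, GPR180, a G protein-coupled receptor family member, and SS18, a subunit of the BAF chromatin remodelling complex. The names of the 4 probe sets of SS18 all end in _s_at or _x_at. GPR180 fell 1.99-fold (-0.99 ± 0.096, adjusted p = 0.0221) and SS18 1.62-fold (-0.69 ± 0.066, adjusted p = 0.0221). No gene rose, and 434 genes had an unadjusted p below 0.05, where 679 are expected by chance. SS18 lost its call when any of the 8 arrays was left out (adjusted p from 0.0657 to 0.404), and GPR180 when any was left out (0.0718 to 0.283) except replicate 1 of the control siRNA group without glucose (0.0152). The change itself stayed between -0.72 and -0.67 for SS18 and between -1.14 and -0.84 for GPR180. In a fit of only these 2 groups neither GPR180 (adjusted p = 0.331) nor SS18 (0.263) was called, nor was either without a filter on dim probe sets (0.0655 for both). With the mean of its probe sets GPR180 was not called (-0.72, adjusted p = 0.0804). With glucose, GPR180 differed by -0.58 and SS18 by -0.56 on the same probe sets, neither of them called. None of 46 complex I genes (median 0.00075) and none of 30 NAD metabolism genes (median -0.0037) was called. Camera called NRF2 targets lower (adjusted p = 0.00309, median -0.053), with none of 26 members called, and leukocyte markers lower (adjusted p = 0.0224, 7 members, none called). Neither passed with an estimated correlation (adjusted p = 0.645 for both), and without a filter the leukocyte markers lost the call (0.799).

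Averaged over both media, SRC-1 knockdown lowered 4 genes and raised none. Beside NCOA1 (-3.16 ± 0.077) these were GPR180 (-0.78 ± 0.068, adjusted p = 0.00902), SS18 (-0.63 ± 0.047, adjusted p = 0.00420) and KLHL5, a member of the kelch-like family (-0.58 ± 0.060, adjusted p = 0.0264). Each was lower on all 4 knockdown arrays than on the control arrays of the same medium. SS18 kept its call when each array was left out in turn (highest adjusted p 0.0457). GPR180 lost it without either array of control siRNA with glucose, or any of the 4 knockdown arrays (0.0578 to 0.0867), and KLHL5 lost it without any array (0.0948 to 0.259) but replicate 2 of SRC-1 siRNA without glucose (0.0371). The averaged change stayed between -0.86 and -0.71 for GPR180 and between -0.63 and -0.53 for KLHL5. KLHL5 was also not called without a filter on dim probe sets (adjusted p = 0.0651) or with the mean of its probe sets (-0.37, adjusted p = 0.597). A total of 674 genes had an unadjusted p below 0.05, where 679 are expected by chance. The averaged changes of the complex I list (median 0.0088), complexes II to V (0.014), the TCA cycle (0.011), glycolysis (0.022), NAD metabolism (0.013) and the regulators of mitochondrial biogenesis (0.014) held no called member, and neither camera nor fry, in a single direction or mixed, called these lists. NDUFS1 differed by -0.015 (95% interval -0.13 to 0.10), NDUFV1 by 0.054 (-0.08 to 0.19) and NAMPT by -0.064 (-0.23 to 0.10). Camera called NRF2 targets (adjusted p = 0.0428) and leukocyte markers (adjusted p = 0.0262) lower, and neither passed with an estimated correlation (adjusted p = 0.980 and 0.913) or with quantile normalization (0.128 and 0.0569). Across genes the knockdown effects in the 2 media had a Pearson correlation of 0.135, or 0.0715 without NCOA1, and they shared no array.

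The interaction asks whether glucose acted differently once SRC-1 was lowered. No gene passed in limma, and 465 had an unadjusted p below 0.05, where 679 are expected by chance, but 802 did when replicate 2 of control siRNA with glucose was left out. The smallest p with a glucose effect shifted upwards under SRC-1 siRNA belonged to RLN2 (0.58 ± 0.095), TAF6L (0.62 ± 0.13), C9orf72 (0.64 ± 0.14), FOXN3 (0.45 ± 0.10) and TRIM21 (0.43 ± 0.099). Those shifted downwards were TRARG1 (-0.62 ± 0.11), ESRRB (-0.48 ± 0.089), DPEP3 (-0.53 ± 0.099), TMIE (-0.54 ± 0.10) and ABCG4 (-0.74 ± 0.15), and none of these 10 passed (adjusted p = 0.999 for each). For the ER list the median interaction was 0.018, for complex I 0.01 and for NAD metabolism 0.047, and neither camera nor fry, in a single direction or mixed, called any of the 36 lists. HSPA5 had an interaction of 0.13 (95% interval -0.071 to 0.34) and DDIT3 of 0.045 (-0.23 to 0.32). For 99.7% of genes the 95% interval lay within a 2-fold change, and for 89.6% within a 1.5-fold change. In simulated arrays with 200 changed genes the interaction recovered 98.6% of 2-fold but 60.1% of 1.5-fold differences.

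Markers of RNA quality and of other cell types were read beside these groups. The 3' minus 5' signal of GAPDH was higher by 0.027 on the 4 arrays with glucose than on the 4 without (two-sided exact permutation test, p = 0.0571), and that of beta-actin by 0.093 (exact permutation p = 0.143). For the 4 knockdown arrays against the 4 control arrays the differences were -0.012 (exact permutation p = 0.343) and 0.0036 (exact permutation p = 0.943). With 4 arrays against 4 such a p cannot lie below 0.0286. Of epithelial markers, 3 were higher and 2 lower of 10 with glucose and control siRNA, among them KRT19 (0.57 ± 0.083) and CLDN1 (-0.99 ± 0.093). Of 6 fibroblast markers only LUM (0.64 ± 0.15) was called, and of 7 leukocyte and 5 endothelial markers none was.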

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

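The tests of too little precision, of NCOA2 and of other probe sets and the beta-actin covariate were chosen only after the results were seen. The heat shock and Wnt lists described further below were also chosen after seeing the data. The other tests were chosen before. The genes DPEP3, PROZ, TMIE and TRARG1 were called higher with glucose under control siRNA and lower under SRC-1 siRNA, with the 2 arrays of each group apart from those of the other medium. The difference between their glucose effects was -0.53 for DPEP3, -0.42 for PROZ, -0.54 for TMIE and -0.62 for TRARG1 on the log2 scale. None passed the interaction test over 13584 genes (limma adjusted p = 0.999), and 465 genes had an unadjusted p below 0.05, where 679 are expected by chance, or 802 without replicate 2 of control siRNA with glucose. A total of 1379 probe sets outside the main measurement, tied to several genes or to none in the annotation used, were called for the glucose effect with control siRNA. Of these, 482 of 1191 were tied to several genes and 897 of 3173 were not listed, and no such probe set was called for SRC-1 knockdown.

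The small response to SRC-1 knockdown stood against the loss of NCOA1 mRNA by about 9-fold on its brightest probe set. Its other probe sets fell between 4.02-fold and 6.21-fold. For 99.9% of genes the 95% interval of the averaged effect lay within 1.5-fold, which speaks against imprecision as the reason that no larger changes were called, though changes below 1.5-fold remain open. In simulated arrays 55.2% of 1.2-fold changes were recovered for the averaged effect. The upper end of the interval of NCOA2 was 0.18 on the log2 scale, which excludes a 1.5-fold rise of that mRNA. Quantile normalization called 4 genes, but the deposited arrays already shared a scale, so this cannot show a change of all genes that scaling removed, and that stays open. Of 34 splits of the arrays into 4 and 4 with glucose in the fit, 1, the real split, called as many as 4 genes. The highest of the others called 0. The count of 4 includes the siRNA target NCOA1, which the real split was bound to call. Some of the other splits are not balanced over the media as the real split is, and so have less power. The comparison therefore does not exclude chance for the genes beside NCOA1. Of the same splits, 20 of 34 had as many genes at an unadjusted p below 0.05 (687 in the real split, 382 to 1075 in the others). That range is too wide to tell whether many small changes exist, although the test was set to count a value inside it against them. The SRC-1 protein left after transfection, its activity and the time allowed for a response were not analysed here and stay open.

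SS18, GPR180 and KLHL5 were called lower with SRC-1 siRNA averaged over both media. With glucose alone none of them was called, without glucose KLHL5 was not, and leaving out single arrays ended the averaged call of GPR180 in 6 of 8 fits and of KLHL5 in 7 of 8, with changes of -0.86 to -0.71 and -0.63 to -0.53. A single odd probe set is argued against, since 87.5% (7 of 8) of their other probe sets above the filter fell as well, and 6 of these 8 were lower on every knockdown array than on every control array of the same medium. KLHL5 had the exception, a probe set with an averaged change of 0.038. The names of all 4 probe sets of SS18 end in _s_at or _x_at, so a shared target of these is not excluded for SS18. The falls may be a response to SRC-1 or an effect of the siRNA on other mRNAs. The siRNA sequence was not used here and no rescue is in the design, so these cannot be separated.

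The glucose response of ER and G1/S genes was weighed against RNA quality. The beta-actin 3' minus 5' signal of each array was entered as a covariate. With it the gap between the medians of the 2 lists kept 102% of its size (2.37 against 2.33 on the log2 scale). This argues only against a cause that beta-actin reads, and the fitted slope rests on differences between the 2 arrays of a group. The GAPDH signal, with a smaller exact permutation p between the media (0.0571 against 0.143), was not tried as a covariate. RNA quality is therefore not excluded. Glucose is the difference that the design names between these groups, and whether it acted directly or through slower growth was not tested.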

How the results depend on the processing

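The covariate on beta-actin and the heat shock and Wnt lists were chosen after seeing the data, and the other alternatives before. The glucose effects called between 4518 and 6538 genes without a fold threshold, against 6142 and 6070, and between 4271 and 6066 of these were shared with the calls of the report. A 1.5-fold threshold left 2014 and 2005. With the covariate they called 4704 and 5342 genes. SRC-1 knockdown with glucose called 1 gene, except 2 with the filter at the 60th percentile and 3 with the prior that follows mean expression. Without glucose it called 3, but 1 without a filter, 1 in a fit of only the groups compared, 4 with the filter at the 60th percentile, 2 with the mean of probe sets, 2 without cross-hybridizing probe sets, 5 with that prior, and 1 to 2 when an array was left out. Averaged, it called 4, but 3 without a filter, with the mean of probe sets, without cross-hybridizing probe sets and at 1.5-fold, 7 with that prior, and 2 to 3 when an array was left out. A lone array left in a group is assumed to vary like the other groups. The extra genes were not named here, and the cause was not tested. The interaction called 0 genes throughout. The replicate numbers were not used as pairs in the main fit, as same-numbered arrays had correlations of deviations between -0.096 and 0.12. These low values do not exclude that same-numbered arrays were handled together. With a replicate block the knockdown without glucose called 1 gene, the average 3, and the glucose effects 6075 and 5993. Among 375 named genes by comparison, probe set choice turned the sign of 10. Without cross-hybridizing probe sets these were, with control siRNA, GINS2 (-0.00046), KRT7 (0.12), NAMPT (0.040), NDUFV3 (0.15) and UQCR11 (0.096), and with SRC-1 siRNA, GINS2 (-0.027), NDUFV3 (0.23), RPL14 (0.025) and UQCR10 (-0.20), and with the mean of probe sets NRF1 (-0.035) with control siRNA. A further 85 sign changes concerned genes called under neither setting. With SRC-1 siRNA, camera called NRF2 targets higher with glucose under quantile normalization (adjusted p = 0.0414) and also without a filter, and the TCA cycle with the mean of probe sets (0.0149). With that mean it also called TGF-beta and YAP targets (0.0135) and G1/S genes (0.0451) lower for knockdown without glucose, and TGF-beta and YAP targets (0.0293) for the average. The estimated correlation ended 28 list calls, and fry in a single direction called 25 lists in each glucose effect and none for knockdown or interaction. Mixed fry called 33 and 34 lists in the glucose effects, 3, 1 and 1 for knockdown with glucose, without it and averaged, and 0 for the interaction. The correlation of the glucose effects was 0.984 among the 3396 brightest genes and that of the knockdown effects 0.110. No pseudocount was tried, since the table is on a log scale. Dim genes have no detection call, which limits them.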

Other observations

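Other lists held called members with glucose, without a call of the list by camera. Of all tested genes 45.2% were called with control siRNA, and the NRF2 and ribosome biogenesis lists had a smaller share. With control siRNA, 10 of 23 interferon-stimulated genes were higher and 3 lower, including IFIT1 (1.44 ± 0.13), PARP9 (1.03 ± 0.081), OAS3 (1.01 ± 0.090) and USP18 (0.58 ± 0.061), at a list adjusted p of 0.207. Of 22 p53 targets, 8 were higher and 7 lower, with the DNA repair gene DDB2 at 0.71 ± 0.070 and the stress gene GADD45A at -2.19 ± 0.074. Of 20 glucocorticoid targets, 5 were higher and 10 lower, with FKBP5 at 1.21 ± 0.096 against TSC22D3 at -1.52 ± 0.064 and IGFBP1 at -1.92 ± 0.10. Of 22 hypoxia targets, 8 were higher, such as EGLN3 (1.68 ± 0.12), and 5 lower, such as VEGFA (-1.09 ± 0.082). NRF2 targets had 7 higher and 1 lower of 26, the exception being the transporter ABCC3 (-0.91 ± 0.065), and ribosome biogenesis 4 and 4 of 22. Fry in a single direction called the p53 (adjusted p = 0.00163), glucocorticoid (0.00224), interferon (0.00398) and NRF2 (0.0367) lists, and not hypoxia (0.0787) or ribosome biogenesis (0.480), which mixed fry called (2.37e-06 and 1.50e-05).

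Both hypotheses below were written after the first look at the data and before their own tests. Unless stated, the p of their lists is adjusted together with the 36 other lists of the comparison, a choice made after the results were seen. The first was that the high HSPA6 signal without glucose came with a general heat shock response. A list of 21 tested heat shock genes, without HSPA6, had a median of 0.24 with glucose and control siRNA, with 10 higher and 2 lower. The median lay on the side opposite to what the hypothesis needs, although the list was not called by camera (adjusted p = 0.173, or 0.0974 over the 2 added lists alone). Only these 21 of 25 listed genes could be tested. HSPA1A and HSPA1B were not among them, so the list does not speak for these genes. With control siRNA, DNAJA1 was at 0.76 ± 0.15 (SE, n = 2 per group), HSPH1 at 0.039 ± 0.13 and DNAJB1 at -0.42 ± 0.18, the last 2 not called. The 2 members called lower with glucose, as HSPA6 was, were SERPINH1 (-0.66 ± 0.10) and CRYAB (-0.29 ± 0.073). With SRC-1 siRNA the list was called higher with glucose (adjusted p = 0.0289, and 0.705 with an estimated correlation). For knockdown without glucose the list had a median of -0.084, no member called and a camera adjusted p of 0.0670 (0.0106 over the 2 added lists alone). With an estimated correlation these were 0.977 and 0.545. The second was that Wnt targets respond to glucose, from the rises of AXIN2 and RNF43. The 14 other tested targets had a median of 0.18 with 5 higher, among them ZNRF3 (1.59 ± 0.090) and FZD7 (0.83 ± 0.13), and 1 lower, JAG1 (-0.51 ± 0.073). The list was not called (adjusted p = 0.205, and 0.458 with an estimated correlation, or 0.0974 and 0.313 over the 2 added lists alone), so the test leaves the question open.

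TXNIP, which many cell types raise strongly with glucose, differed by -0.22 ± 0.11 with control siRNA and 0.013 ± 0.11 with SRC-1 siRNA.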
